A study of Mus musculus with 4 samples.

How the data were processed

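The series holds single-cell RNA sequencing of CD11b-positive cells from the mouse brain, from 4 libraries with 1 mouse each. The labels give wild-type and IL-6 knockout mice after sham surgery or at day 6 after cerebrovascular injury, which was made by pulsed ultrasound with intravenous microspheres under a thinned skull window. The sample characteristic places the control mice 6 days after sham surgery, whereas the extraction protocol calls them uninjured. Tissue came from a 4 mm punch. Cells were dissociated, myelin was removed, and CD11b-positive cells were taken with microbeads, so the shares of cell classes are set in part by that selection. The labels describe a mild and a severe injury but do not say which was used for these mice, and they do not name the targeted Il6 exon. Libraries were made with the 10x 3′ v3 chemistry and sequenced with the aim of 150 M reads and 4000 cells each.

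The deposited matrices hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 6.0.1 on mm10 per the file headers and the labels. All values are whole numbers. Of the 32285 gene identifiers, 32158 (99.6%) are in the GENCODE vM21 annotation of GRCm38, which gave the positions. The authors' own annotation release is not given in the sources used here. The identifiers share 78 duplicate symbols, and 2 of 361 genes on the fixed lists, Clec7a and Mx1, were not among the symbols.

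Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. Doublets were scored in each library with Scrublet, and the highest scored cells were left out at a rate of 0.8% per 1000 barcodes. Counts were scaled to 10000 per cell and logged, 2000 variable genes were chosen among those detected in at least 10 cells, and 30 principal components and 15 neighbours entered Leiden clustering at resolution 1 with seed 0. Cell cycle, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes were left out of clustering, as were 113 further genes whose level correlated above 0.25 with the cell cycle lists. No integration across libraries was used. The 18 clusters were named from 160 marker genes in 16 fixed marker lists. A cluster took the class whose markers were detected in the largest share of its cells, with at least 3 markers detected. A cluster stayed unnamed when its 10 leading genes (detected in at least 25% of its cells, ranked with a prior of 20 CPM) held more markers of another class, or when it was shallow without a marker of its own among them. A cluster with a marker detection share of at most 0.6 could take the class of its leading genes. This left 6 microglia clusters and 5 unnamed clusters. Among the unnamed, 2 carry microglia markers but have a macrophage or monocyte marker among their leading genes. They are kept out of the microglia-like class, and values with them added are printed beside the lead results.

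Each comparison sets single libraries against each other without replicates, so no p-values are given. A test of the injury across both genotype labels, which the 4 libraries would allow with few degrees of freedom, was not run. For each class and library, raw UMI counts were summed over cells and divided by their total to give CPM. A CPM carries an exact Poisson 95% interval, a ratio of 2 libraries an exact conditional binomial 95% interval, and a share of cells an exact Clopper-Pearson 95% interval. These intervals, and the floor of 3 counts used for a value of 0, cover counting error only and not differences between mice. A fold against a library with 0 UMIs is a lower bound against that floor. Log2 ratios use a prior of 10 CPM on both sides. A gene was called at least 2-fold higher or lower from the log2 ratio if it had at least 20 CPM in 1 of the libraries compared and at least 50 UMIs over the 4 libraries. Comparisons were injury against sham in each genotype, knockout-labelled against wild type after injury and after sham surgery, and the difference of the 2 injury effects, in which the log2 ratio of the wild type is subtracted from that of the knockout-labelled pair. Other classes were compared where both libraries had at least 50 cells. The correlation of the 2 injury effects is across genes, which are not independent replicates.

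The 16 gene lists were fixed before the data were examined, as were the markers, the comparisons and the alternative settings. They cover homeostatic microglia, disease-associated microglia, angiogenic growth factors and vascular remodelling, the IL-6 receptor and signal transducers, STAT3 targets, S phase, G2/M phase, interferon response, MHC class II, MHC class I, inflammatory cytokines and chemokines, phagocytosis and complement, iron and heme handling with oxidative stress, glycolysis and hypoxia, cholesterol and lipid handling, and dissociation-responsive immediate early genes. For each list the median log2 ratio of its measured members was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list stands apart below the 2.5th or above the 97.5th percentile, which is relative to those random lists and describes these libraries only. Members were counted as higher or lower at 1.5-fold on the log2 ratio, and as between otherwise.

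Named genes follow a fixed rule. Genes passing the CPM and UMI minimums in microglia-like cells were ranked by log2 ratio, and the 10 highest and 10 lowest were taken for injury in the wild type and for knockout-labelled against wild type after injury. The 5 highest and 5 lowest were taken for the other 2 comparisons, and the 6 highest and 6 lowest for the difference of the injury effects. Mitochondrial, ribosomal protein, haemoglobin, sex-linked, immunoglobulin and T cell receptor genes and clone names were left out. Il6, Il6ra, Il6st, Socs3, Stat3, Vegfa, Mki67, Top2a, Apoe and Spp1 are reported in microglia-like cells whatever their rank, each list gives up to 4 members with the largest absolute log2 ratio, and other classes give 5 genes in each direction. Some genes that meet these rules are not reported here. Shares of cells with a UMI were measured after thinning each cell to 2000 UMIs, and shallower cells were left out of them. A cell counted as cycling with at least 3 UMIs from the G2/M list.

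The count procedure was tested on simulated data made from the wild-type microglia-like counts. Of 50 genes each, 98% with a simulated 4-fold decrease, 80% with a 3-fold decrease, 100% with a 3-fold increase and 100% with a 4-fold increase were called at least 2-fold different in the right direction. Among 5289 genes left unchanged, 0 were called. The ratio interval held the true ratio for 95.6% of 1000 genes, 4.25% of 400 random lists stood apart on unchanged counts, and 2 of 2 lists with simulated changes were called in the right direction. The simulated counts hold counting error only, without differences between mice, cells or clusters. They check the procedure and do not show how often libraries of like mice would differ.

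The alternatives set in advance were a looser filter (200 genes, 500 UMIs, 20% mitochondrial) and a stricter one (1000 genes, 2000 UMIs, 5%), no doublet removal and 2 times the doublets left out, clustering resolutions of 0.5 and 2, and microglia taken cell by cell (at least 2 microglia markers and at most 1 marker of other myeloid cells). Scaling alternatives were median-of-ratios factors, CPM without mitochondrial and ribosomal genes, cells weighted equally, and cells thinned to 2000 UMIs. Minimums of 20 and 200 UMIs, priors of 2 and 50 CPM, 2 UMIs for cycling, no thinning, thinning to 1000 UMIs and 10 expression bins were also run. Chosen after the data were seen were the microglia-like class with the 2 unnamed clusters added, and the injured wild-type library set against the sham library labelled knockout. Work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

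Depth differed between libraries. The wild-type sham library held 4425 barcodes with a median of 1399 UMIs, of which 73.7% exceeded 10% mitochondrial UMIs, and 957 cells were analysed. The injured wild-type library held 4731 barcodes (median 5865 UMIs, 31.9% over that limit) and 2883 analysed cells. The knockout-labelled sham library held 2682 barcodes (median 3592 UMIs, 40.9%) and 1362 analysed cells, and the injured one 4202 barcodes (median 5315.5 UMIs, 32.2%) and 2549 analysed cells. Doublet removal had taken 35, 113, 30 and 89 cells in the same order. Analysed cells had median depths of 7638, 10016, 8106.5 and 8443 UMIs. In the summed microglia-like counts the floor of 3 counts lies at 0.450, 0.215, 0.321 and 0.187 CPM.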

Results

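Single-cell RNA sequencing was compared between 4 libraries of CD11b-positive cells from the mouse brain, from wild-type and IL-6 knockout mice after sham surgery or at day 6 after cerebrovascular injury. The comparisons ask which genes of microglia, the resident macrophages of the brain, differ after the injury, and which of these differ in mice labelled as lacking the cytokine IL-6. Each group is 1 mouse and 1 library, so there are no replicates, and every value describes these libraries. Summed counts are given in CPM, relative to all UMIs of the class.

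Il6, which encodes the cytokine that the knockout should remove, was detected in all 4 libraries and was higher in both libraries labelled knockout. Over all analysed cells it held 99 UMIs in the wild-type sham library (10.6 CPM, 95% interval 8.58 to 12.9), 164 in the injured wild-type library (4.65 CPM, 3.96 to 5.42), 324 in the knockout-labelled sham library (25.3 CPM, 22.7 to 28.3) and 542 in the injured knockout-labelled library (22.02 CPM, 20.2 to 24.0). The knockout-labelled level was 2.40-fold (1.91 to 3.04) the wild-type one after sham surgery and 4.74-fold (3.97 to 5.68) after injury. In microglia-like cells the ratios were 1.91 (1.47 to 2.50) and 2.73 (2.21 to 3.39). The unthinned share of these cells with Il6 was alike after sham surgery, at 10.6% (8.14 to 13.5) in the wild type and 11.8% (9.70 to 14.1) in the knockout-labelled library. After injury it was 5.35% (4.19 to 6.72) and 12.5% (10.8 to 14.3). The sham cells held 80 UMIs in 58 cells and 214 UMIs in 103 cells, with up to 15 in 1 knockout-labelled cell. Counting intervals assume no such clumping and are too narrow for Il6. Endothelial-like cells held Il6 UMIs in 14 of 48 and 16 of 134 cells of the knockout-labelled sham and injured libraries. None of 28 and 81 endothelial-like cells of the wild-type libraries did, which allows shares of up to 10.7% and 3.70%. The macrophage, monocyte or dendritic-like class had 57.3 and 44.5 CPM of Il6 in the knockout-labelled sham and injured libraries against 1.25 (1 UMI) and 3.05 CPM in the wild-type ones. The make-up of that class differs between libraries, and within its Gpnmb and Lyz2 cluster Il6 was 10.7 CPM (5.13 to 19.7) in the injured knockout-labelled library and 2.42 CPM (1.51 to 3.66) in the injured wild type. Il6 (ENSMUSG00000025746) lies on chromosome 5 at 30013114 to 30019981 on the + strand of the mm10 genome. The counts per gene come from 3′ tags and the targeted exon is not given in the sources used here, so they do not check the genotype. The libraries are therefore called knockout-labelled, and a direction between genotypes is a direction between labels.

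Macrophages and monocytes made up a larger share of the injured wild-type library than of the other 3 libraries. The macrophage, monocyte or dendritic-like class, named from markers such as Ccr2, Ms4a7, Mrc1 and Cd209a, held 10.6% (8.68 to 12.7) of analysed cells in the wild-type sham library and 21.3% (19.8 to 22.8) in the injured one. In the knockout-labelled libraries it held 5.07% (3.96 to 6.37) after sham surgery and 6.36% (5.44 to 7.37) after injury. Most of the excess was a cluster marked by Gpnmb and Lyz2, with 485 cells (16.8%) in the injured wild-type library, 81 (3.18%) in the injured knockout-labelled one, and 17 and 8 cells in the sham libraries. Some microglia markers were found in this cluster, with P2ry12 in 49.4%, Tmem119 in 49.2% and Olfml3 in 83.8% of its cells (median 15233 UMIs). The shares in endothelial-like cells (median 4862 UMIs) were 14.8%, 7.56% and 15.1%, and none of these is corrected for depth. Other microglia markers were sparse, with Sall1 in 10.2% (14.8 CPM) and Siglech in 17.1% (39.2 CPM) of its cells. Microglia-like cells had 208 and 738 CPM of these. P2ry12 was also found in 51.2% of border-associated macrophage-like cells, so it does not set microglia apart here. The cluster was named from Lyz2 and Ms4a7 among its leading genes. Border-associated macrophage-like cells (Mrc1, Pf4, Cd163) were 7.84%, 1.98%, 3.89% and 2.31% of the wild-type sham, injured wild-type, knockout-labelled sham and injured knockout-labelled libraries. A dendritic or monocyte-like cluster with high H2-Aa held 2, 60, 2 and 16 cells in the same order, and a Ly6c2 and Ccr2 monocyte-like cluster 7, 12, 6 and 6 cells. Microglia-like cells made up 57.3% (54.1 to 60.4), 44.7% (42.9 to 46.6), 64.3% (61.7 to 66.9) and 56.8% (54.8 to 58.7), from 548, 1290, 876 and 1447 cells. Neutrophil-like cells were 1.25%, 1.35%, 0.441% and 0.275%, endothelial-like cells 2.93%, 2.81%, 3.52% and 5.26%, and neural-like cells 2.30%, 1.04%, 2.42% and 1.73%.

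Unnamed clusters held 25.7%, 28.8%, 24.2% and 29.6% of the cells in the same order. One of them, led by Cd5l and Spp1, had no cells in either sham library, which allows up to 0.313% and 0.220%, and 398 (13.8%) and 39 (1.53%) cells in the injured wild-type and knockout-labelled libraries. Another, led by Ifi27l2a (a monocyte marker on the fixed list and an interferon-induced gene), had 0.522%, 11.9%, 0.734% and 18.6%. Ifi27l2a was the 1 macrophage, monocyte or dendritic cell marker among its leading genes. Its microglia markers lay near those of the microglia-like class, with Sall1 at 178 against 208 CPM and Siglech at 733 against 738 CPM. P2ry12 was found in 96.6% of its cells, Ms4a7 in 3.13% and F13a1 in 0.361%. Ccr2 was 2.08 CPM, against 2.57 CPM in microglia-like cells. Cells with microglia markers and neuronal transcripts such as Snap25 and Meg3 were 10.2%, 0.486%, 12.1% and 0.785%, and shallow cells 14.9%, 2.53%, 11.4% and 8.75%. Microglia-like cells with the Cd5l and Ifi27l2a clusters added made up 57.8%, 70.5%, 65.1% and 76.9%. The microglia-like share is thus lower after injury without these clusters and higher with them, under both labels. Values for this wider class are given beside the lead results because Spp1, Cd5l and Ifi27l2a are also among the genes compared. Within the microglia-like class, sham cells lay mostly in clusters led by Hspa1b and P2ry12 (37.0% and 49.1% of the wild-type and knockout-labelled sham cells) by Slc5a3 and Ints6 (41.8% and 20.7%) or by Hspa1b and P2ry13 (12.6% and 22.8%). Injured cells lay mostly in clusters led by Il1a and Gpr84 (35.8% and 45.1%) or by Lpl and Cst7 (38.7% and 20.2%). Most of the others lay in clusters led by Hspa1b and P2ry12 (11.8% and 15.5%), which also holds many sham cells, and by Ifit3 and Cxcl10 (8.22% and 12.5%). The clusters led by Slc5a3 and Ints6 (2.40% and 2.00%) and by Hspa1b and P2ry13 (3.10% and 4.63%) held the rest.

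**Figure D1:**
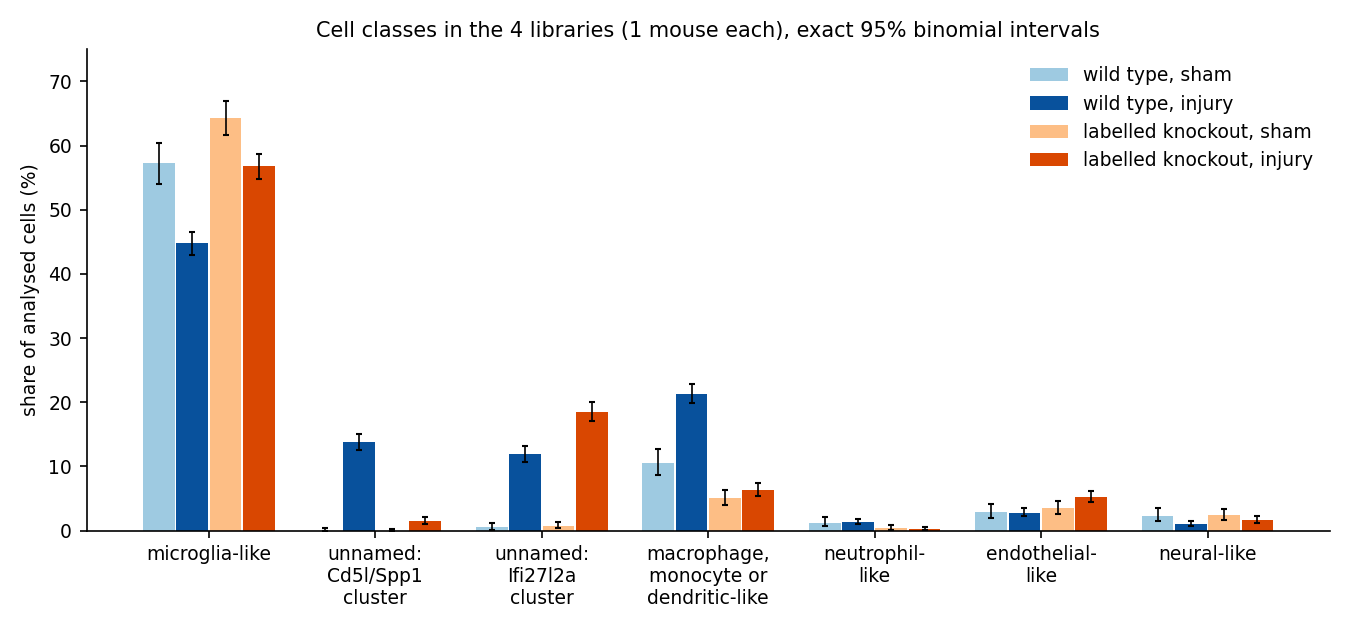
Share of analysed cells (%) in 7 groups of cells (x axis) for the 4 libraries, 1 mouse each, with bars for the share and lines for its exact 95% binomial interval. The macrophage, monocyte or dendritic-like class is 21.3% of the injured wild-type library and 6.36% of the injured knockout-labelled one.

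After injury, microglia-like cells of the wild-type mouse carried far more RNA of Spp1, Apoe and Igf1 and less RNA of the chaperone genes Hspa1b and Hspa1a than those of the sham mouse. Spp1, which encodes the secreted matrix protein osteopontin, was 2.70 CPM in the sham library and 4102 CPM in the injured one, a ratio of 1518 (960.2 to 2561). Apoe, a lipid carrier, was 57.4-fold higher (633 against 36279.7 CPM, interval 55.6 to 59.1). The lysosomal inhibitor gene Cst7 was 47.7-fold higher (36.6 to 63.4), the growth factor gene Igf1 45.03-fold (32.2 to 65.1), and the fatty acid carrier gene Fabp5 58.2-fold (42.7 to 81.6). Ifi27l2a, a monocyte marker on the fixed list, was 41.7-fold higher (33.7 to 52.3), the antiviral Ifitm3 31.9-fold, the lipase Lpl 20.9-fold, and the apolipoprotein Apoc1 114-fold (55.0 to 283). Gpnmb, a lysosomal glycoprotein, went from 1 UMI to 112 CPM, a ratio of 746 with a counting interval of 134 to 29479. Lower in the injured library were the chaperones Hspa1b (9.001-fold, 7.78 to 10.5) and Hspa1a (3.98-fold), both on the dissociation-responsive list, the osmolyte transporter Slc5a3 (5.93-fold), the Notch target Hes1 (7.08-fold), the adaptor Bank1 (8.46-fold) and the growth factor Hbegf (5.14-fold). The fructose transporter Slc2a5 (4.10-fold), the transcription factor Zfhx3 (3.54-fold), the cytokine receptor Lifr (4.95-fold) and the phosphatase Dusp7 (3.93-fold) were also lower. The summed markers of monocytes and monocyte-derived cells, Lyz2 the most abundant, were also higher in these microglia-like cells after injury, at 639 against 3123 CPM. Of 5921 genes, 206 were at least 2-fold higher and 349 at least 2-fold lower.

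The balance of that count depends on the scaling. Median-of-ratios factors move the median of all genes from -0.19 to 0.01 in this comparison and from -0.15 to 0.00 in the knockout-labelled one, and the counts become 405 higher and 81 lower (83.3% higher in place of 37.1%). Cells weighted equally give 165 higher and 148 lower (52.7% higher). Against the knockout-labelled sham library in place of the wild-type one, 222 genes were at least 2-fold lower. With the 2 unnamed clusters added, 255 were higher and 576 lower, of which 188 and 346 are genes of the first counts, and Spp1 was 1770-fold (1309 to 2456), Apoe 73.9-fold, Igf1 83.0-fold and Fabp5 139-fold higher.

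By gene list, the homeostatic microglia genes were lower after injury in the wild type and the disease-associated genes higher. Of 20 homeostatic genes, 18 were at least 1.5-fold lower and 0 higher (median log2 -0.997), with the ectoenzyme Entpd1 3.07-fold and the receptor P2ry13 2.92-fold lower. Of 23 disease-associated genes, 22 were higher and 0 lower (median 1.84). Interferon response genes were higher in 25 of 29 (median 1.92), with the transcription factor Irf7 30.2-fold and the DNA sensor Ifi204 16.7-fold higher. Cytokine and chemokine genes were higher in 17 of 21 (median 1.48), with Il1b 6.61-fold (6.25 to 6.997) and Cxcl2 5.78-fold higher. G2/M genes were higher in 22 of 37 (median 0.70), with the kinase Cdk1 10.6-fold (6.79 to 17.5) higher and Mki67 going from 2 UMIs to 23.1 CPM, a ratio of 77.0 (21.1 to 638). S phase genes (median 0.35) were higher in 5 of 27 and lower in 2. MHC class I genes were higher in 7 of 13 (median 0.68), with H2-D1 2.39-fold and H2-K1 2.12-fold higher. Glycolysis and hypoxia genes (median 0.77, 13 of 20 higher) had Mif 3.16-fold and Pgk1 2.85-fold higher. Lipid genes (median 0.63) were higher in 9 of 18, phagocytosis and complement genes (0.34) in 7 of 22, with the scavenger receptor Msr1 8.87-fold and the complement component C3 16.3-fold higher. Angiogenic and vascular remodelling genes (median 0.26) were higher in 8 of 25 and lower in 3, with the phospholipid-binding Anxa2 23.4-fold and the matrix gene Fn1, a monocyte marker on the fixed list, 53.0-fold (24.2 to 145) higher. Iron and heme genes (median 0.09) had the superoxide-producing oxidase subunit Cybb 6.31-fold higher and the transferrin receptor Tfrc 3.24-fold lower.

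The remaining 4 lists did not stand apart from random lists in the wild-type injury comparison. IL-6 receptor and transducer genes had a median of -0.55, with the receptor chain Il6ra 2.57-fold (2.40 to 2.74) lower and Il6st 1.67-fold lower. Stat3 was 1.92-fold (1.79 to 2.05) lower. STAT3 targets had a median of -0.15 (0.22 under median-of-ratios scaling), with the cyclin Ccnd1 2.89-fold lower, Hif1a 2.09-fold higher and Socs3, an inhibitor induced by STAT3, at a ratio of 1.01 (0.967 to 1.05). Over all settings the log2 ratio of Socs3 ranged from -0.48 to 0.42, so its direction here depends on the processing. MHC class II genes had a median of 0.04, with 3 of 12 higher, among them H2-Ab1 3.97-fold. Dissociation-responsive genes had a median of -0.23 (0.18 under median-of-ratios scaling), with 3 of 24 higher and 9 lower.

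**Figure D2:**
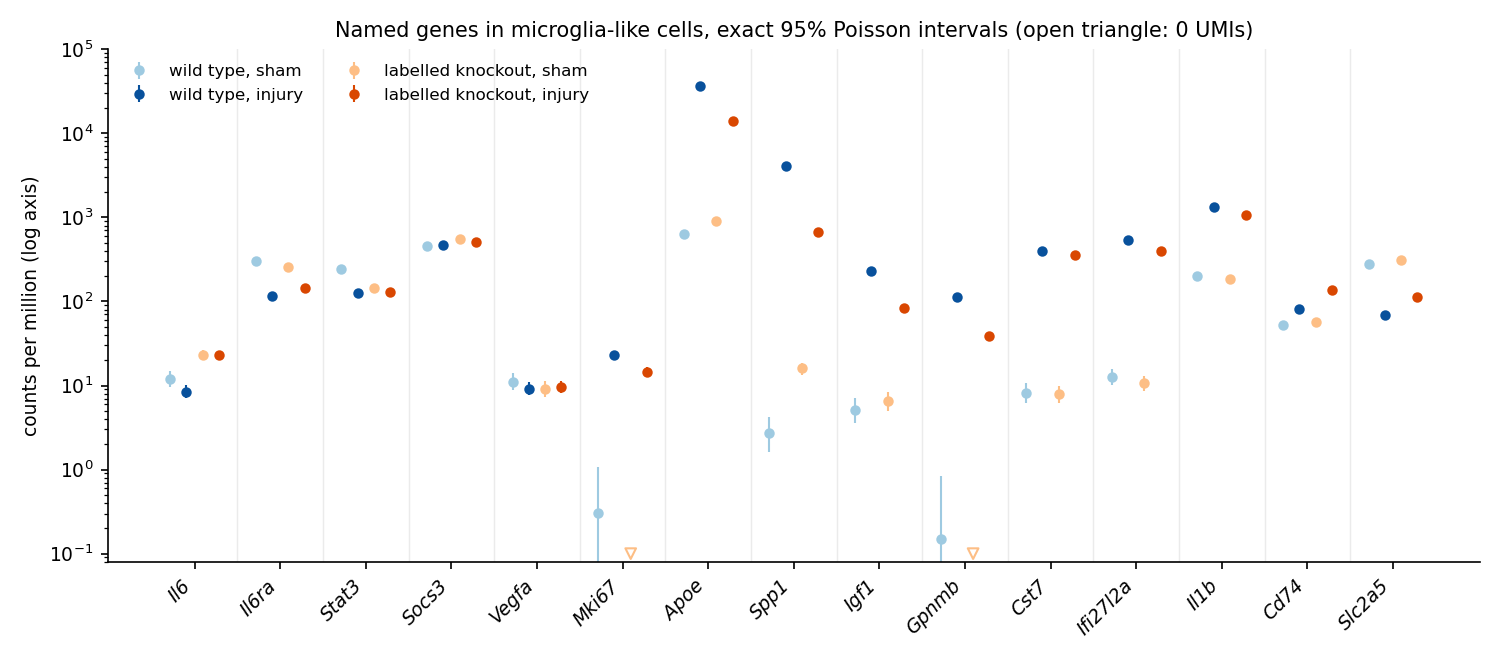
Summed counts in CPM (log axis) of 15 genes in microglia-like cells of the 4 libraries, 1 mouse each, with points for the value, lines for its exact 95% Poisson interval, and an open triangle where no UMI was found. Spp1 is 4102 CPM in the injured wild-type library and 678 CPM in the injured knockout-labelled one, whereas Cst7 is 394 and 359 CPM.

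In the knockout-labelled pair the injured library was higher for many of the same genes. Spp1 was 42.5-fold (36.2 to 50.3) higher, Cst7 45.4-fold (36.1 to 57.9), the monocyte marker Ifi27l2a 37.6-fold (30.8 to 46.3), Ifitm3 34.4-fold (28.2 to 42.5) and Apoe 15.4-fold (15.1 to 15.8). The lowest were Hspa1b (17.6-fold, 15.01 to 20.7), Hspa1a (5.43-fold), Hes1 (6.9998-fold), the arrestin-related Arrdc3 (6.89-fold) and Hbegf (6.35-fold). Of 5884 genes, 168 were at least 2-fold higher and 70 at least 2-fold lower (70.6% higher). Median-of-ratios scaling gave 244 and 28 (89.7%), and cells weighted equally 140 and 41 (77.3%). With the 2 unnamed clusters added the counts were 160 and 87, of which 148 and 66 are genes of the first counts, and Spp1 was 75.5-fold and Apoe 16.7-fold higher.

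The same lists stood apart as in the wild type, and MHC class II genes did so in addition. The summed monocyte markers were also higher in these microglia-like cells after injury, at 607 against 2163 CPM (Lyz2 316 against 1365 CPM). Homeostatic genes were lower in 15 of 20 (median -0.77), with Txnip, a regulator of glucose uptake, 3.25-fold lower. Disease-associated genes were higher in 22 of 23 (median 1.89), interferon genes in 27 of 29 (2.07), with Ifit3 30.9-fold and Slfn5 39.7-fold higher, and cytokine genes in 16 of 21 (1.34), with the chemokine Ccl5 45.5-fold (27.0 to 83.5) higher. G2/M genes were higher in 20 of 37 (0.61), with Birc5 79.6-fold (21.8 to 661, from 2 UMIs) and Mki67 at least 45.3-fold higher. MHC class II genes (0.24) had Cd74, the invariant chain, 2.40-fold higher and MHC class I genes (0.64) H2-Q7 4.36-fold. Glycolysis genes (0.75) were higher in 14 of 20, lipid genes (0.33) in 7 of 18, with the hydroxylase Ch25h 29.2-fold higher, phagocytosis genes (0.29) in 6 of 22, angiogenic genes (0.34) in 7 of 25, iron genes (0.17) in 4 of 19 and S phase genes (0.17) in 2 of 27. IL-6 receptor genes (-0.21), STAT3 targets (0.02) and dissociation-responsive genes (-0.20, and 0.09 under median-of-ratios scaling) did not stand apart, although with the 2 unnamed clusters added the last of these did as lower (-0.44). Il6ra was 1.76-fold (1.66 to 1.87) lower, Il6st 1.31-fold lower, and Stat3 and Socs3 had ratios of 0.887 (0.829 to 0.951) and 0.931 (0.899 to 0.964), both of which pass above 1 under median-of-ratios scaling.

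Across 6099 genes the 2 injury effects correlated with a Pearson r of 0.916 and a Spearman rho of 0.876, and the slope of the knockout-labelled effect on the wild-type one was 0.72. Of these genes, 157 were at least 2-fold higher in both pairs (207 in the wild type, 177 in the knockout-labelled pair) and 63 at least 2-fold lower in both (351 and 70).

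**Figure D3:**
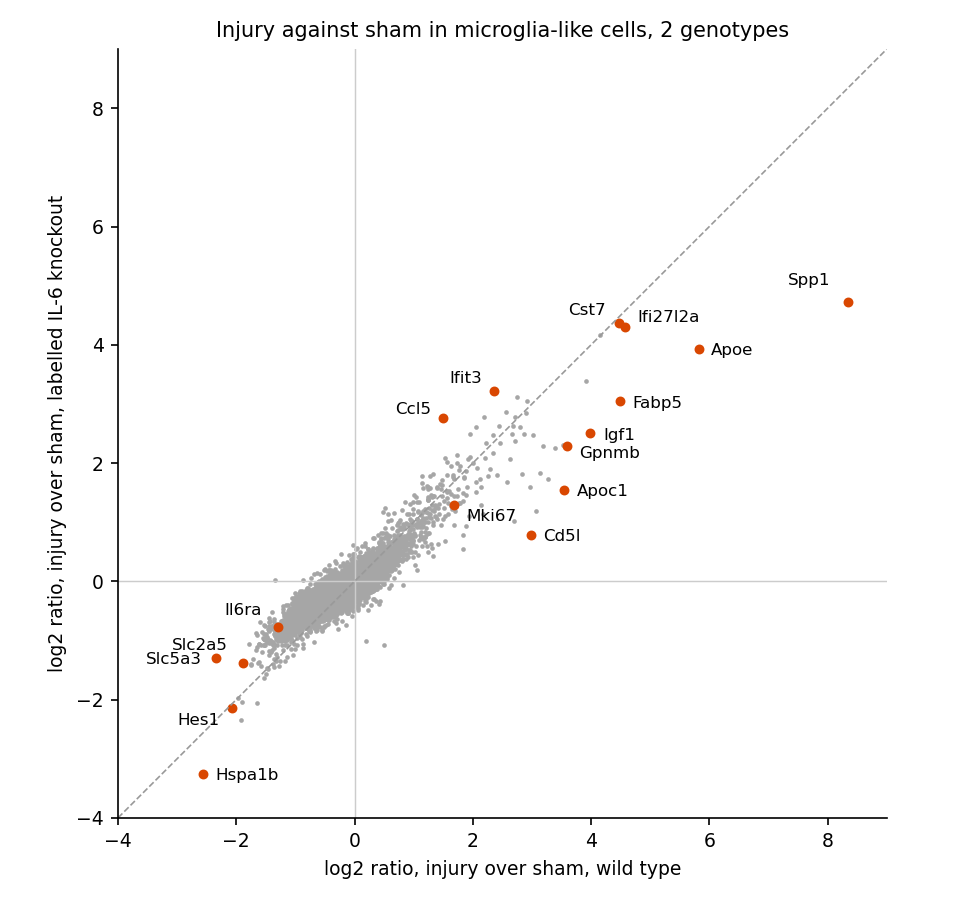
Log2 ratio of injured over sham library in microglia-like cells, wild type (x axis) against knockout-labelled (y axis), with 1 grey point per gene, named genes in orange and the line of equality dashed. Spp1 and Apoe lie at 8.34 and 5.82 in the wild type and at 4.73 and 3.93 in the knockout-labelled pair.

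After injury, microglia-like cells of the knockout-labelled library held less RNA of Spp1 and of apolipoprotein genes than those of the wild type. Spp1 was 6.05-fold (5.92 to 6.17) lower, at 678 against 4102 CPM, and Apoe 2.57-fold (2.56 to 2.59) lower, at 14097 against 36279.7 CPM. Cd5l, a secreted macrophage protein, was 8.89-fold (7.37 to 10.8) lower, and the apolipoproteins Apoc1, Apoc2 and Apoc4 were 5.35-fold (4.77 to 6.02), 3.69-fold (3.29 to 4.15) and 5.52-fold (4.29 to 7.17) lower. The secreted Wfdc17 was 5.67-fold, the folate receptor Folr2, a border-associated macrophage marker on the fixed list, 5.29-fold, Igf1 2.74-fold (2.57 to 2.92) and Gpnmb 2.87-fold (2.61 to 3.15) lower. Higher in the knockout-labelled library were Il6 itself, the protease Klk8 (1.80-fold), the checkpoint receptor Lag3 (1.68-fold), Cd74 (1.68-fold, 1.56 to 1.80) and the homeostatic genes Selplg (1.60-fold) and Slc2a5 (1.64-fold). The lectin Siglecf (1.74-fold), the GTPase Gbp2 (1.96-fold), the RNA-binding Khdrbs3 (1.86-fold) and the chemokine Ccl9 (1.52-fold) completed the 10 highest. Of 5217 genes, 0 were at least 2-fold higher and 18 at least 2-fold lower. This count uses the log2 ratio with its prior of 10 CPM, which the folds above do not carry. Without the prior Il6 was 2.73-fold (2.21 to 3.39) higher.

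With the 2 unnamed clusters added to the microglia-like class, the same genes were lower by more. For Cd5l, Spp1 and Igf1 this follows from the addition and is no further support. They lead the added Cd5l and Spp1 cluster, which holds 398 injured wild-type and 39 injured knockout-labelled cells. Spp1 was 9.28-fold (9.16 to 9.40), Apoe 3.06-fold, Igf1 4.62-fold (4.395 to 4.85), Cd5l 19.0-fold (17.1 to 21.2) and Gpnmb 3.25-fold lower, and Cd74 was 2.27-fold higher. There, 5 genes were at least 2-fold higher and 43 lower, and 17 of the 18 above are among the 43.

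Among the lists, homeostatic genes were higher in the knockout-labelled injured library and disease-associated genes lower. Markers of other myeloid cells were lower in the same microglia-like cells, at 2163 against 3123 CPM for the summed monocyte markers (Lyz2 1365 against 2093 CPM) and 140.1 against 291 CPM for those of border-associated macrophages, such as Stab1. The homeostatic median was 0.30, with 19 of 20 members above 0 but only 2 at least 1.5-fold higher, and Serinc3 and Rhob at 1.41-fold and 1.38-fold. The disease-associated median was -0.15, with 6 of 23 lower and 0 higher, Fabp5 being 2.30-fold (2.19 to 2.42) lower. Lipid genes (median -0.18) were lower in 4 of 18, with the lipid droplet protein Plin2 2.55-fold lower. Angiogenic and vascular remodelling genes (-0.07) were lower in 4 of 25 and higher in 0, with Spp1, Igf1, Anxa2 (1.82-fold) and the monocyte marker Fn1 (1.71-fold) the 4 lower ones. MHC class II genes (0.26) were higher in 2 of 12, with H2-Oa 1.64-fold and H2-Ab1 1.48-fold higher. G2/M (-0.11) and S phase (-0.10) genes had 0 members past 1.5-fold once the prior of 10 CPM is added, and before it Tpx2, a spindle protein, was 1.97-fold and Mki67 1.59-fold (1.34 to 1.89) lower. Iron genes (-0.10, Ftl1 1.28-fold lower), phagocytosis genes (-0.03, Gas6, a bridging ligand for dying cells, 1.57-fold lower) and cytokine genes (-0.04, Ccl7 3.45-fold and Ptgs2 1.56-fold lower) stood apart as lower. IL-6 receptor genes had a median of 0.15 with 12 of 12 members above 0, at the 96.57th percentile, short of standing apart. STAT3 targets (0.06), interferon genes (0.08), MHC class I genes (0.08), glycolysis genes (0.03) and dissociation-responsive genes (0.04) did not stand apart, and under median-of-ratios scaling these 5 medians were -0.03, -0.00, -0.01, -0.05 and -0.06. Ifit3 was 1.42-fold (1.32 to 1.53) higher, Socs1 1.42-fold higher, Socs3 1.10-fold (1.06 to 1.14) and Il6ra 1.25-fold (1.18 to 1.34) higher, and Stat3 had a ratio of 1.02 (0.960 to 1.09). In the wider class the homeostatic median was 0.50 with 6 members higher, the MHC class II median 0.50 with 5 higher, the disease-associated median -0.16 with 7 lower and the angiogenic median -0.13 with 6 lower. There IL-6 receptor genes (0.23), STAT3 targets (0.21) and interferon genes (0.16) stood apart as higher and glycolysis genes (-0.04) as lower, and cytokine genes (0.14) did not stand apart. Iron genes (-0.24) and G2/M genes (-0.23) had 3 members lower each and phagocytosis genes (-0.04) 4.

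**Figure D4:**
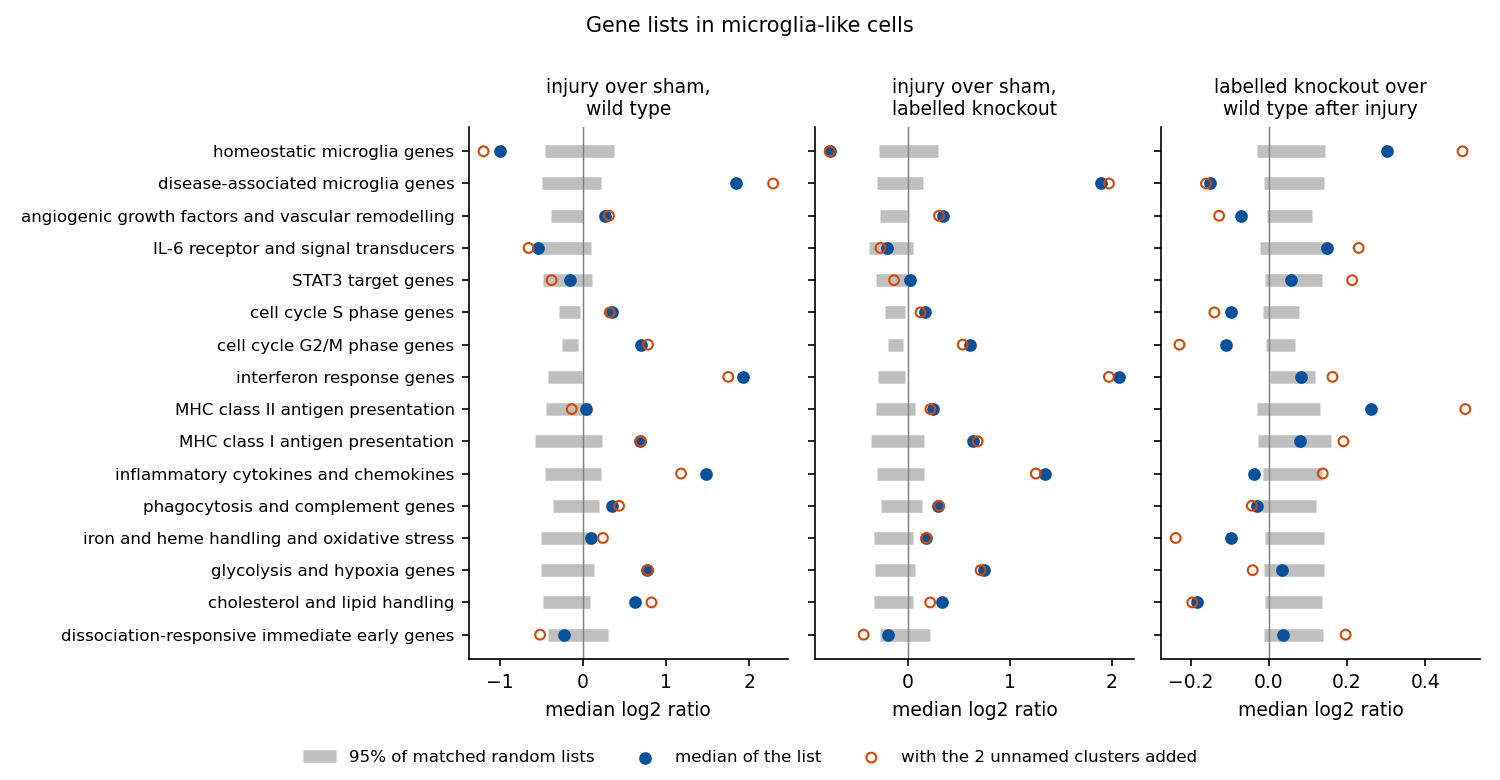
Median log2 ratio (x axis) of 16 gene lists in microglia-like cells for 3 comparisons of libraries, with filled points for the microglia-like class, open circles for that class with the 2 unnamed clusters added, and grey bars for 95% of 10000 matched random lists. The homeostatic genes lie at -0.997 and -0.77 in the injury comparisons and at 0.30 between the labels after injury.

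After sham surgery the knockout-labelled and wild-type microglia-like cells differed at few genes. Higher in the knockout-labelled library were the detoxifying enzyme Gstp1 (4.25-fold, 3.13 to 5.88), the nuclear Erh (2.22-fold), Khdrbs3 (1.69-fold) and Ttr, a choroid plexus marker on the fixed list (2.94-fold). Lower were the stress cytokine Gdf15 (3.21-fold, 2.68 to 3.86), Iqcn (3.41-fold), the adaptor Baiap2 (2.53-fold), Slc5a3 (2.15-fold) and Ints6 (2.06-fold). Of 5863 genes, 3 were at least 2-fold higher and 4 at least 2-fold lower. These counts use the log2 ratio with its prior of 10 CPM, which the folds given here do not carry. Stat3 was 1.66-fold (1.55 to 1.79) lower, the chemokines Ccl5 (9.02-fold, 5.10 to 17.1) and Ccl7 (4.26-fold) and the prostaglandin synthase Ptgs2 (2.28-fold) were lower, and the matrix protease Mmp12 was at least 9.51-fold higher. Spp1 was 5.90-fold (3.61 to 10.2) higher at 16.0 against 2.70 CPM, Socs3 1.19-fold higher, and Apoe 1.45-fold (1.39 to 1.5001) higher, which turns to lower under the stricter cell filter and when microglia are taken cell by cell. Spp1 and Apoe did not stand above the level in endothelial-like cells in either sham library. Endothelial-like cells had 12.2 CPM (4.89 to 25.1) of Spp1 in the knockout-labelled library and no UMI in the wild type, which allows up to 17.1 CPM, and 1104 and 1000 CPM of Apoe, where microglia-like cells had 914 and 633. Standing apart were disease-associated (median 0.13), MHC class II (0.12) and S phase genes (0.07) as higher, and IL-6 receptor genes (-0.13), STAT3 targets (-0.12) and interferon genes (-0.11) as lower. Past 1.5-fold in that direction were 1 of 23, 0 of 12, 0 of 27, 1 of 12, 1 of 20 and 0 of 29 members, in the same order. These calls depend on the cell filter and the class rule, since 6 lists stood apart here, 2 with the stricter filter and 3 when microglia are taken cell by cell. The median of MHC class II genes reversed to -0.0823 with the looser filter and -0.0801 cell by cell, and interferon genes to 0.0292 cell by cell. Disease-associated genes no longer stood apart at 0.0831 with the stricter filter and 0.0795 cell by cell, nor STAT3 targets at -0.0769 with the looser filter and -0.0865 with the stricter one. The other 10 lists had medians between -0.03 and 0.09.

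The difference between the injury effects was largest for genes that were already among the lowest after injury. On the log2 scale it was -3.61 for Spp1, -2.20 for Cd5l, -2.00 for Apoc1, -1.89 for Apoe, -1.88 for Wfdc17 and -1.68 for the border-associated macrophage marker Folr2. The highest were Iqcn (1.36), Ccl5 (1.26), Slc5a3 (1.05), Ints6 (0.93), the repressor Bcl6 (0.90) and Meg3, a neuronal marker on the fixed list (0.89). For Iqcn, Slc5a3 and Ints6 the injured libraries were close (13.6 and 14.99, 47.4 and 47.6, and 80.7 and 77.0 CPM) and the difference lies between the sham libraries. For Spp1, -2.58 lies between the injured libraries, and 1.03 between the sham libraries, where its level is not above that in endothelial-like cells. Of 6099 genes, 3 were at least 2-fold higher and 20 at least 2-fold lower. Homeostatic (0.24), IL-6 receptor (0.32, Stat3 0.73 and Il6ra 0.51) and MHC class II genes (0.20) stood apart as higher. For Stat3 most of this lies between the sham libraries. Over all settings its log2 ratio between labels was -0.77 to -0.58 after sham surgery and -0.06 to 0.25 after injury. Between labels the IL-6 receptor median was -0.13 after sham surgery, standing apart, and 0.15 after injury, not standing apart. Disease-associated (-0.30), lipid (-0.24), S phase (-0.17), G2/M (-0.09), phagocytosis (-0.09) and angiogenic genes (-0.08) stood apart as lower. The G2/M median is 0.0171 with the stricter cell filter, and the angiogenic one 0.00507 without doublet removal and 0.0138 at clustering resolution 2, and at each of these values that list does not stand apart. With cells thinned to 2000 UMIs 5 of the 9 lists are left, and the homeostatic genes (0.10), MHC class II genes (0.16), phagocytosis genes (-0.10) and angiogenic genes (-0.10) no longer stand apart. The other 7 lists had medians from -0.04 for iron genes to 0.14 for STAT3 targets. With the 2 unnamed clusters added, STAT3 targets (0.32), cytokine genes (0.28) and interferon genes (0.22) stood apart as higher and iron genes (-0.10) as lower, and the medians were 0.43 for homeostatic, -0.41 for lipid and -0.21 for G2/M genes. No interaction test is possible with 1 library per group.

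In the Gpnmb and Lyz2 macrophage cluster, the knockout-labelled injured library (81 cells) held more MHC class II RNA and less Spp1 than the wild type (485 cells). H2-Eb1 was 11.5-fold (10.7 to 12.4), Cd74 9.54-fold (9.11 to 9.99), H2-Ab1 9.44-fold and H2-Aa 9.42-fold higher. Ttr, a choroid plexus marker, was 48.2-fold higher in this cluster, and over all barcodes it was 1862 CPM in the injured knockout-labelled library against 30.9 CPM in the injured wild type. Spp1 was 5.63-fold (5.42 to 5.84), Cd5l 9.91-fold (5.52 to 19.9) and the phagocytic bridge protein Mfge8 8.90-fold (4.67 to 19.5) lower. The neuropeptide Gal and the arginase Arg1, a monocyte-derived cell marker, had no UMI in the knockout-labelled library and were at least 13.3-fold and 10.9-fold lower. Of 5160 genes, 88 were at least 2-fold higher and 51 lower. MHC class II genes (median 1.23) were higher in 10 of 12, cytokine genes (0.67) in 13 of 21, homeostatic genes (0.72) in 12 of 20 and interferon genes (0.47) in 10 of 29. STAT3 targets (0.41, 4 of 21 higher and 1 lower) and MHC class I genes (0.42, 3 of 13 higher) stood apart as higher. Dissociation-responsive genes (0.38), which respond to handling of the tissue, also stood apart as higher, in 10 of 24. G2/M genes (-0.61) were lower in 11 of 19, lipid genes (-0.57) in 8 of 17, disease-associated genes (-0.35) in 5 of 23 and angiogenic genes (-0.22) in 6 of 22. Glycolysis genes (-0.16, 2 of 19 lower) and iron genes (-0.11, 0 of 19) stood apart as lower too. Socs3 was 1.69-fold (1.44 to 1.97) higher.

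Border-associated macrophage-like cells numbered 75 and 57 in the wild-type sham and injured libraries and 53 and 59 in the knockout-labelled ones. After injury the wild type had Lgals3, a lectin, 83.3-fold (22.6 to 694) higher, Gpnmb at least 90.1-fold, the monocyte marker Fn1 at least 64.4-fold, Igfbp5 56.8-fold and the fibroblast marker Col3a1 33.1-fold higher, while H2-Ab1 (8.53-fold), Cd74 (7.71-fold) and H2-Aa (6.71-fold) were lower, as were the choroid plexus marker Ttr and the matrix gene Coch, both with no UMI after injury. MHC class II genes were lower in 6 of 8 (median -1.93), whereas in the knockout-labelled pair they were higher in 4 of 8 and lower in 0 (0.39). The knockout-labelled pair had the interferon genes Irf7 18.9-fold and Rsad2 12.6-fold higher after injury, with interferon genes higher in 24 of 26 (1.38) against 7 of 26 (0.27) in the wild type, Igfbp7 at least 40.0-fold, Mgp 92.5-fold (from 1 UMI, 16.3 to 3687) and the fibroblast marker Dcn 15.3-fold higher. Hspa1b (5.21-fold), the dendritic cell marker Cd209a (5.61-fold), the stress gene Gadd45g (4.93-fold), the lectin Mgl2 (3.88-fold) and Arrdc3 (3.90-fold) were lower. Between labels after injury, Rsad2 was 9.13-fold (5.12 to 17.7), Ifit2 5.69-fold, Ifit1 5.44-fold and Igfbp7 5.37-fold higher in the knockout-labelled cells, and Ttr at least 18.9-fold. Fn1 and Igfbp6 were at least 50.8-fold and 24.2-fold lower, and the collagen genes Col1a1 (45.02-fold), Col3a1 (31.3-fold), both fibroblast markers, and Col4a1 (25.3-fold) were lower. Socs3 was 2.70-fold (1.90 to 3.89) higher, and interferon genes (0.62) were higher in 14 of 26, MHC class II genes (0.75) in 4 of 8 and STAT3 targets (0.54) in 8 of 17, whereas angiogenic genes (-0.42) were lower in 7 of 19. Dissociation-responsive genes also stood apart as higher in the knockout-labelled cells, in 8 of 23 after injury (0.33) and in 8 of 23 after sham surgery (0.53). After sham surgery the cytokines Tnf (2.62-fold) and Il16 (2.86-fold), Gadd45g (2.72-fold), Kansl1l (2.48-fold) and Arrdc3 (2.47-fold) were higher in the knockout-labelled cells. Lower were Mgp (391-fold, 70.0 to 15477, from 1 UMI), Igfbp7, Coch and Alpl, each with no UMI, and the differentiation inhibitor Id3 (14.4-fold), and MHC class II genes were lower in 6 of 8 (-1.06) and interferon genes, unlike after injury, in 8 of 26 (-0.41).

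Endothelial-like cells could be compared after injury only (134 knockout-labelled against 81 wild-type cells). The mural cell markers Vtn and Kcnj8 were 5.25-fold and 7.20-fold higher in the knockout-labelled cells, the hormone Prl at least 17.2-fold, the clock gene Dbp 4.84-fold and the oligodendrocyte marker Mbp 4.63-fold. Spp1 (16.1-fold), the prostaglandin synthase Ptgds (15.6-fold), the monocyte marker Lyz2 (7.67-fold), Il1b (5.78-fold) and Timp2 (3.47-fold) were lower, as were phagocytosis genes in 6 of 10 (-0.97), a group of myeloid genes. Disease-associated genes (-0.65, 8 of 15 lower) and homeostatic microglia genes (-0.39, 4 of 15 lower) also stood apart as lower. Spp1 was 473 CPM in the wild-type and 29.4 CPM in the knockout-labelled cells, and Lyz2 359 and 46.8 CPM. Endothelial-like Spp1 is used here as the background of free RNA. Lower myeloid genes therefore need not be differences of endothelial cells, and free RNA was not tested for them. In the Ifi27l2a cluster (473 against 344 cells) the chemokines Cxcl13 (11.1-fold, 5.69 to 24.6) and Cxcl9 (at least 17.3-fold) were higher in the knockout-labelled cells, with the oxidase Il4i1 2.10-fold, Fbxl14 2.11-fold and Klhl7 1.83-fold higher. Lgals3 (3.84-fold), the border-associated macrophage marker Folr2 (3.05-fold), the centromere gene Cenpa (3.19-fold), Cxcl2 (2.16-fold) and Apoe (2.15-fold, 2.13 to 2.18) were lower. There MHC class II genes (0.37, 0 of 9 past 1.5-fold) and homeostatic genes (0.18, 1 of 20) stood apart as higher. G2/M genes (-0.51, 5 of 12 lower), lipid genes (-0.08, 2 of 16) and dissociation-responsive genes (-0.07, 0 of 24) stood apart as lower.

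Vegfa, the main growth factor for vessels, stayed close to 10 CPM in microglia-like cells of each library, and no difference was detectable at this depth. It was 11.1, 9.19, 9.21 and 9.56 CPM in the wild-type sham, injured wild-type, knockout-labelled sham and injured knockout-labelled libraries, with ratios of 0.827 (0.616 to 1.12) for injury in the wild type, 1.04 (0.792 to 1.37) in the knockout-labelled pair and 1.04 (0.817 to 1.33) between labels after injury. With the 2 unnamed clusters added the wild-type ratio was 0.562 (0.423 to 0.752) and the ratio between labels after injury 1.41 (1.13 to 1.76). At 2000 UMIs per cell, 1.54%, 1.36%, 1.79% and 1.27% of microglia-like cells had a Vegfa UMI, against 0 of 27, 1.32%, 0 of 47 and 0 of 122 endothelial-like cells. Those zeros allow up to 11.1%, 6.38% and 2.46%, so the shares cannot be set above that background. In the Gpnmb and Lyz2 macrophage cluster Vegfa was 43.2 CPM in the injured wild-type library and 16.0 CPM in the injured knockout-labelled one, a ratio of 0.371 (0.206 to 0.620), and 8.73% (42 of 481) and 1.23% (1 of 81) of its cells had a UMI at 2000 UMIs. Il6ra was found in 42.7%, 22.7%, 38.1% and 26.5% of microglia-like cells at 2000 UMIs against 3.70%, 10.5%, 12.8% and 9.02% of endothelial-like cells. Cells with both Vegfa and Il6ra were 0.385%, 0.160%, 0.955% and 0.425%.

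Spp1 was found in 44.4% of microglia-like cells and 44.7% of endothelial-like cells of the injured wild-type library at 2000 UMIs, so that share is at background, and its excess lies in the amount per cell (4102 against 473 CPM). In the injured knockout-labelled library the shares were 14.7% and 5.74%. The share of microglia-like cells with at least 3 G2/M UMIs was 10.0% (7.56 to 12.9), 9.50% (7.93 to 11.3), 6.56% (4.98 to 8.46) and 7.43% (6.12 to 8.92). It does not follow Top2a, a topoisomerase of dividing cells, which was 14.1-fold (7.79 to 28.6) higher after injury in the wild type and 13.0-fold (7.61 to 24.0) in the knockout-labelled pair, so no order of cycling is read from it.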

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

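The tests of dilution by uninjured microglia, of free Il6 RNA and of exchanged labels were chosen after the result was seen, and the tests of depth, of free Spp1 RNA, of reads outside the targeted exon and of a linked segment before.

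Of the genes reported in the microglia-like cells, 3 moved in opposite directions after injury in the wild-type and knockout-labelled pairs, beyond their counting intervals. For Erh the ratio of injury to sham was 1.45 in the wild type and 0.727 in the knockout-labelled pair, a ratio of 2.00 between them. The ratios were, for the MHC class II chaperone H2-DMa, 0.9204 and 1.13 (0.816 between them) and, for the growth inhibitor Btg2, 0.977 and 1.03 (0.953). Under median-of-ratios scaling H2-DMa (1.23 and 1.39) and Btg2 (1.30 and 1.26) lie above 1 in both pairs, and only Erh (1.93 and 0.894) stays opposite. None was 1.5-fold in both pairs, and the difference was not tested because each group is 1 library.

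Haemoglobin transcripts, which stand in no comparison, were counted in the injured libraries above the level in the sham ones. Over all barcodes there were 3718 haemoglobin UMIs in the injured wild-type library and 3774 in the injured knockout-labelled one, against 12 and 11 in the sham libraries. Of these, 3707 came from 2 barcodes and 3767 from 3 barcodes.

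The injured knockout-labelled library had fewer macrophages, and its microglia-like cells less Spp1 and Apoe, than the injured wild type. A difference in depth per cell is excluded as the whole source of the differing share of cells with both Ms4a7 (a border-associated macrophage marker) and Gpnmb. At 2000 UMIs per cell that share was 10.3 times higher (7.36 to 14.7) in the wild type. Without the unnamed Cd5l and Spp1 cluster, which also holds such cells, it was 9.67 times higher (6.73 to 14.4), at 13.1% against 1.35%. Both genes lead the Gpnmb and Lyz2 cluster, so the share reflects their level per cell as well as the number of cells. Depth was not tested for the other macrophages. Free RNA is excluded as the whole source of Spp1, which was 8.67 times higher (7.69 to 9.80) in microglia-like than in endothelial-like cells of the injured wild type. Dilution by uninjured microglia is excluded as the whole cause of the lower Apoe in microglia-like cells. The median log2 ratio over 205 injury genes was -0.16 (-0.22 to -0.12), where a mix matching Apoe (62.7% uninjured) would give a median of -0.75. That interval comes from resampling the genes, which are not independent, and does not cover differences between mice. The quartiles over these genes were -0.41 and 0.01. A smaller share of uninjured microglia was not tested and is not excluded. Open explanations are such a smaller dilution, a punch that missed the macrophage-rich core, the severity of the lesion, differences between mice and the genotype. With 1 mouse per group no value here separates them.

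Il6 transcripts were present in the libraries labelled knockout. Free RNA spread over the droplets is excluded as their whole source in microglia-like cells, because 29 of these cells held at least 5 Il6 UMIs where chance gives 0.404. Free RNA as a part of the Il6 counts was not tested. Endothelial-like cells held 73.0 and 46.8 CPM in the knockout-labelled sham and injured libraries, against 22.9 and 23.1 CPM in microglia-like cells. Reads from outside the targeted exon (542 Il6 UMIs in the injured knockout-labelled library) and genotype labels exchanged between libraries (99 Il6 UMIs in the wild-type sham library) cannot be told apart, because counts per gene hold no reads per exon. If the labels were exchanged, each direction between genotypes given here would turn around.

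Few genotype differences were shared by sham and injured microglia-like cells. Ptgs2, Ccl7, Khdrbs3, Ttr (a choroid plexus marker), the nuclear receptor Nr4a3 and Gdf15 were the 6 genes other than Il6 that differed at least 1.5-fold the same way in both. They lie on chromosomes 1, 11, 15, 18, 4 and 8 in that order, and 0 of 86 genes within 15 Mb of Il6 on chromosome 5 are among them. Their chromosomes alone exclude a linked segment around the targeted locus as the place of these genes. Random windows with as many measured genes held a median of 0 and at most 1 of them, so the count of 0 near Il6 adds nothing. Effects of such a segment on genes elsewhere were not tested.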

How the results depend on the processing

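Of the alternatives, adding the 2 unnamed clusters to the microglia-like class and setting the injured wild type against the knockout-labelled sham library were tests chosen after the result was seen. A test of the injury across both genotype labels, paired or not, was not run. Within a label no pairing is possible because each group is 1 library from 1 mouse. For the same reason no library was left out in turn.

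The lead results kept their direction under each alternative. Spp1 and Apoe were lower in the injured knockout-labelled library throughout, with Spp1 between -3.20 and -2.48 and Apoe between -1.79 and -1.15 on the log2 scale, Cd5l between -3.63 and -1.04, Igf1 between -2.09 and -1.06 and Gpnmb between -2.27 and -0.86, and Cd74 was higher between 0.08 and 1.30. Apoe was higher after injury between 5.29 and 6.27 in the wild type and between 3.83 and 4.24 in the knockout-labelled pair. Spp1 moved more, between 6.30 and 9.93 and between 3.47 and 5.76. Other wild-type injury ratios also kept their direction over wide ranges. These were 1.69 to 6.57 for Gpnmb, 2.84 to 5.94 for Fabp5, 2.34 to 5.03 for Igf1 and 2.93 to 5.27 for Cst7. Between the sham libraries Apoe ranged from -0.28 to 0.64, so its direction there is not kept. Of 1216 list medians under alternatives, 1124 stayed on their side of the threshold, 14 reversed, 40 became stronger and 38 weaker, and the cause was not tested except where given.

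The shares of cells moved with the filter and the class rule. With the looser filter microglia-like shares were 36.6%, 34.0%, 49.8% and 46.3% in the wild-type sham, injured wild-type, knockout-labelled sham and injured knockout-labelled libraries, and the macrophage class 7.73% and 18.7% in the wild-type sham and injured libraries. With the stricter filter microglia-like shares were 73.8%, 78.7% and 64.2% in the wild-type sham, knockout-labelled sham and injured knockout-labelled libraries, and the macrophage class 23.1% of the injured wild type. Taken cell by cell, microglia were 83.5%, 86.5%, 90.5% and 94.3%. In the injured wild type they were 58.3% at clustering resolution 0.5 and 41.9% at resolution 2. With the 2 unnamed clusters added they were 70.5% and 76.9% in the injured libraries, by construction.

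Counts of genes at least 2-fold different in the wild-type injury comparison were 206 higher and 349 lower. The lower count was 598 at resolution 0.5, 624 cell by cell, 576 with the 2 unnamed clusters, 148 with cells weighted equally, 217 with cells thinned to 2000 UMIs, 652 with a prior of 2 CPM and 222 against the knockout-labelled sham library. Median-of-ratios scaling gave 405 higher and 81 lower, and a prior of 50 CPM 86 and 66. In the knockout-labelled pair (168 higher, 70 lower) the lower count was 28 with median-of-ratios scaling, 41 with cells weighted equally and 158 with a prior of 2 CPM, and a prior of 50 CPM gave 70 higher and 14 lower. A larger prior shrinks each ratio, which is the cause for the priors.

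Between labels after injury (0 higher, 18 lower) the counts were 8 and 47 at resolution 0.5, 11 and 63 cell by cell, and 5 and 43 with the 2 unnamed clusters. The stricter filter gave 5 higher, a prior of 2 CPM 1 higher, and a prior of 50 CPM 6 lower. Between labels after sham surgery (3 higher, 4 lower) 8 were lower with the stricter filter, 7 higher cell by cell, 7 lower without mitochondrial and ribosomal genes, 9 lower with cells thinned to 2000 UMIs, 9 lower with a prior of 2 CPM, and 0 higher and 0 lower with a prior of 50 CPM. For the difference between injury effects (3 higher, 20 lower) the counts were 21 and 46 at resolution 0.5, 28 and 71 cell by cell, 9 and 47 with the 2 unnamed clusters, and 0 and 9 with a prior of 50 CPM. There the higher count was 14 with the stricter filter, 5 without mitochondrial and ribosomal genes, 26 thinned to 2000 UMIs and 16 with a prior of 2 CPM.

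Some list medians lost their place or crossed 0. After sham surgery the STAT3 targets (-0.12) were -0.0769 with the looser filter and -0.0865 with the stricter one, the disease-associated genes (0.13) 0.0831 with the stricter filter, 0.0795 cell by cell and 0.0837 with cells weighted equally, and the homeostatic genes (0.08) 0.12 with cells weighted equally and 0.17 thinned to 2000 UMIs. MHC class II genes (0.12) reversed to -0.0823 with the looser filter and to -0.0801 cell by cell, interferon genes (-0.11) to 0.0292 and G2/M genes (-0.03) to 0.0950 cell by cell. The number of lists standing apart there (6) was 2 with the stricter filter and 3 cell by cell.

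Between labels after injury the STAT3 targets (0.06) stood apart at 0.26 at resolution 0.5 and 0.21 with the 2 unnamed clusters. Cytokine genes (-0.04) reversed to 0.21 at resolution 0.5, 0.13 cell by cell and 0.14 with the 2 unnamed clusters, and glycolysis genes (0.03) to -0.0278 at resolution 0.5, -0.0493 thinned to 2000 UMIs and -0.0410 with the 2 unnamed clusters. In the knockout-labelled injury comparison the STAT3 targets (0.02) were 0.0819 with cells weighted equally and 0.17 thinned to 2000 UMIs, and S phase genes (0.17) reversed to -0.0824 thinned to 2000 UMIs. For the difference between injury effects, angiogenic genes (-0.08) were -0.0493 with the stricter filter, 0.00507 without doublet removal, 0.0138 at resolution 2 and -0.10 thinned to 2000 UMIs, where they no longer stood apart. G2/M genes (-0.09) were 0.0171 with the stricter filter and -0.00136 with 2 times the doublets left out, homeostatic genes (0.24) 0.10 thinned to 2000 UMIs, and STAT3 targets (0.14) 0.39 at resolution 0.5 and 0.32 with the 2 unnamed clusters. Lists standing apart (9) were 5 thinned to 2000 UMIs. For each of these the cause was not tested.

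Depth limits the shares of cells with a UMI and the sparse genes. The correlation of the injury effects was 0.783 with cells thinned to 2000 UMIs in place of 0.916, where fewer counts are left. The cycling shares were 24.2%, 23.3%, 18.7% and 19.7% with at least 2 UMIs, 62.2%, 58.9%, 52.5% and 58.8% without thinning, and 3.65%, 3.33%, 1.37% and 2.70% when thinned to 1000 UMIs. At 1000 UMIs Il6ra was found in 25.7%, 13.5%, 22.5% and 15.5% of microglia-like cells, Vegfa in 0.799% of the knockout-labelled sham cells, and Vegfa with Il6ra in 0 of them.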

Other observations

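Ttr, the choroid plexus marker, was 2025 CPM over all barcodes of the wild-type sham library, 30.9 CPM in the injured wild-type one, 3299 CPM in the knockout-labelled sham one and 1862 CPM in the injured knockout-labelled one. The Y-linked gene Ddx3y was 147, 96.0, 134 and 109.6 CPM over all barcodes in the same order, and the X-inactivation transcript Xist held 2, 1, 1 and 3 UMIs. In microglia-like cells the summed neuron markers, Snap25 and Meg3 among them, were 100, 18, 94 and 26 CPM in the wild-type sham, injured wild-type, knockout-labelled sham and injured knockout-labelled libraries.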
